A study of Homo sapiens with 6 samples.

How the data were processed

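Bulk RNA sequencing with poly(A) selection and a stranded library kit was done on CD14+ cells isolated on day 10 from cultures of human CD34+ stem and progenitor cells. The 6 libraries formed 2 groups, untreated (n = 3) and TNF at 10 ng/ml (n = 3), from 4 donors who are separate people. Donor numbers in the labels, replaced here by letters, pair 2 donors (A and B) across the groups, while donors C and D occur in 1 group each.

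The deposited table holds counts, raw numbers of reads per gene, which per the file headers were made with featureCounts 2.0.6 and the Ensembl 110 annotation of GRCh38. The labels name STAR 2.7.11b as the aligner, FastQC for quality control and edgeR 3.28.0. The options in the header set no strand and no counting of pairs, so reads of both strands counted for a gene, each mate of a pair counted as a read, and reads with several alignments or overlapping several genes were left out. Where a gene overlaps an antisense neighbour, reads in the shared stretch are therefore lost to both, which can lower their counts. The table has 62754 genes, 62700 of them with a symbol, and 0 other columns per sample. One gene, ANK2, has no counts because its line is truncated.

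XIST, TSIX and the genes of chromosome Y (603 genes) were removed because the donors are people, which left 62150 genes. Library totals ranged from 18672331 to 41701069 counted reads. A count of 0 allows up to 3 reads of a library's total. Intervals and such limits cover counting error only, since reads without molecular identifiers are not independent molecules. Genes were filtered with filterByExpr by group, which kept 16005, and normalised by TMM. The 2 groups were compared with edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided) in R 4.3.3, as TNF minus untreated, without a replicate block, since this fit uses all 6 libraries. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. The SE printed with a log2 fold change is its absolute value divided by the square root of the test's F statistic. Values per group are TMM-normalised CPM, a gene's reads scaled to a common library size, as mean and SD. The fit with the donor as a fixed replicate block has 1 residual degree of freedom against 4 without it, and its value is printed beside each result whose call it changes. The 30 gene lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01, adjusted over the 29 lists with at least 5 tested members. Principal components used log2 CPM (prior count 2) of the 2000 most variable tested genes. A commonly expressed gene has a median of at least 5 CPM in the other 5 libraries.

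The groups, the comparison, the tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule names up to 12 genes per direction among those past the threshold with a mean of at least 5 CPM, separated groups and the same direction in both shared donors. It took 0 genes, so the 6 genes with the smallest p were named and said not to pass, left out being HLA genes, immunoglobulin and T-cell receptor segments and clone-based names. It also names up to 4 members per list with the smallest p and a fixed panel of TNF, its receptors, CD14, NFKBIA, TNFAIP3, IL1B, CXCL8, CCL2, CCR2, CX3CR1, FCGR3A and CD34. ELANE, ARG1, PRTN3, FN1, COL6A1, COL6A2, S100A12, FPR2, PADI4, MS4A3, C3 and MMP1 fall outside the rule and were chosen after their values were seen.

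In simulated data with 200 changed genes of 16005, the fit without a block recovered 2.99%, 60.7% and 94.9% of genes changed 2-fold, 4-fold and 8-fold, and 7.33% of its calls were false. With the block these shares were 0%, 1.49% and 10.1%, and 30.3% of calls were false. Changed genes were drawn from the more highly expressed ones only. The simulation without a block held no donor differences and no libraries that stand apart, unlike these data. The blocked simulation used donor means and another draw of the dispersion, so the shares of the fits are not directly comparable. Camera called 10 of 10 shifted simulated sets and 0 of 10 random ones. The simulated genes were drawn independently, so this does not check camera where the genes of a list are correlated. As a check of the pairing, the correlation between the 2 libraries of a donor, after removing group means, was −0.0919 for donor A and −0.0869 for donor B, and −0.303 when the 4 libraries of these donors were taken alone. Libraries given the same donor were thus not more alike than others by this measure, and the pairing rests on the labels.

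The alternatives were RLE size factors, library size alone, no and a stricter low-count filter (at least 1 CPM in at least 3 libraries), DESeq2 1.42.0, limma-voom, the donor as a fixed or random block, the 4 libraries of donors A and B, and each library left out in turn. For the lists, camera with an estimated correlation and fry were also run. Added after the data were seen were fits without mitochondrial genes, with counts divided by 2, and other forms of the blocked fit. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.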

Results

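Bulk poly(A) RNA sequencing measured gene expression in CD14+ cells, the monocyte fraction of a culture, grown from human CD34+ blood stem and progenitor cells. The progenitors came from mobilized apheresis products of healthy donors and were kept for 10 days in a medium that expands myeloid cells. They were either left untreated or given tumour necrosis factor alpha (TNF) at 10 ng/ml from day 0, which per the labels mimics the inflammatory bone marrow of chronic kidney disease. There were 3 untreated and 3 TNF libraries from 4 donors. Donors A and B gave a library to each group, donor C an untreated library and donor D a TNF library. The untreated libraries of donors A, B and C held 25450675, 25625870 and 33581999 counted reads, and the TNF libraries of donors A, B and D held 18672331, 41701069 and 32027130.

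Transcripts of the mitochondrial genome took most of the reads in every library, 72.7% ± 5.56 (SD, n = 3) in untreated cells and 64.2% ± 9.32 (SD, n = 3) in TNF cells. The difference gave an exact two-sided permutation p of 0.3, where 3 libraries against 3 cannot give a p below 0.1, and an adjusted p of 0.6 over 6 library measures. MT-CO1, which encodes a subunit of cytochrome c oxidase, alone took between 42.04% and 71.66% of a library's reads, with 95% Wilson intervals at most 0.0448 percentage points wide. Reads from all other genes numbered 6547944 to 12081230 per library. The 4 libraries of donors A and B resembled each other, with correlations of log2 CPM (TMM-normalised counts scaled to library size) across genes between 0.875 and 0.9497, over genes that are not independent replicates. The untreated library of donor C correlated with the others at 0.6787 to 0.7668. It had 0 reads for 11.3% of commonly expressed genes (1282 of 11325; 95% Wilson interval 10.75% to 11.92%), and the TNF library of donor D for 2.72% (307 of 11278; 2.438% to 3.039%). In the libraries of donors A and B that share was 0.8328% or less. On the first principal component, with 61.1% of the variance, the untreated library of donor C lay at −174 and the other 5 between 18.9 and 44.5. The TNF library of donor D lay apart on the second component, at −101.5.

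**Figure D1:**
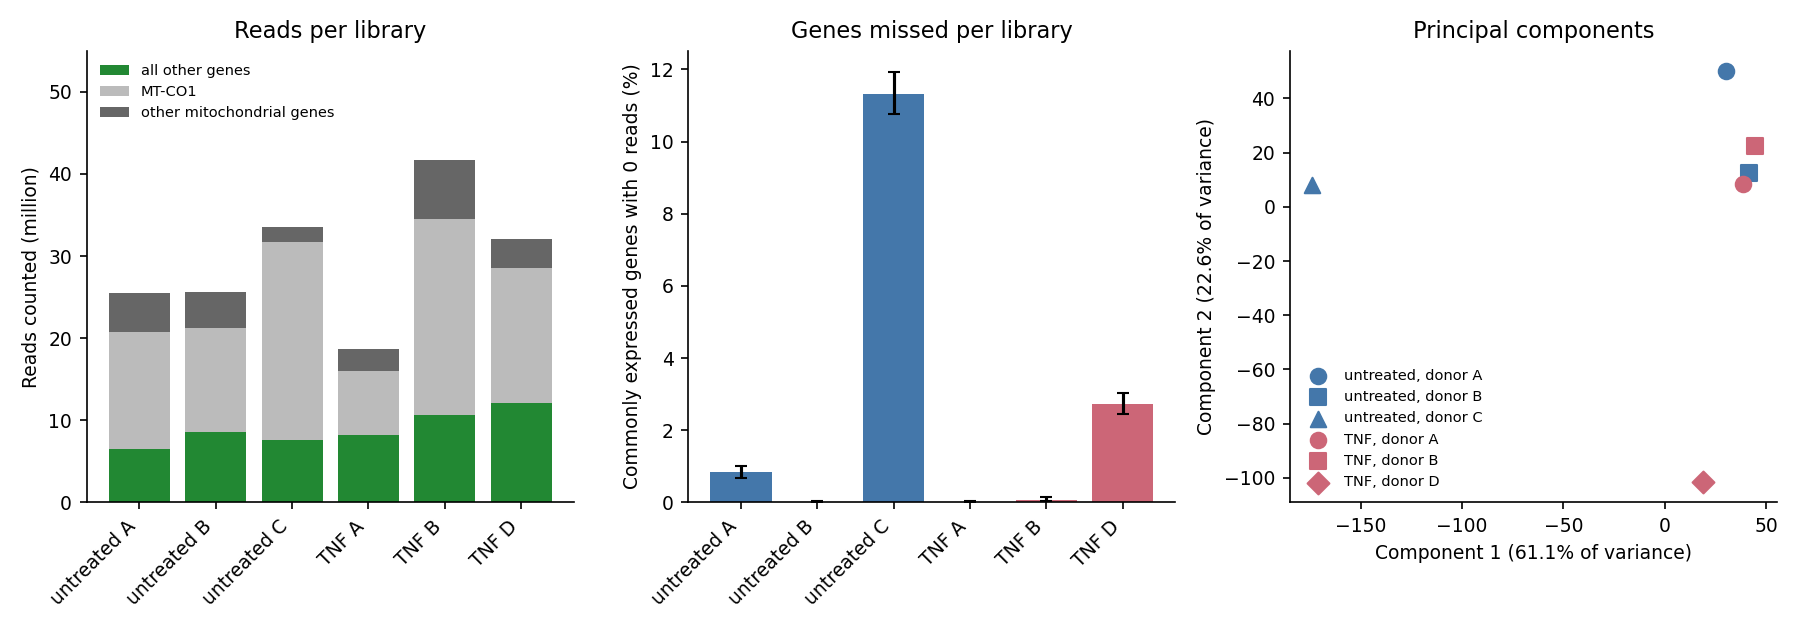
Left, reads counted per library, split into MT-CO1, other mitochondrial genes and all other genes. Middle, percent of commonly expressed genes with 0 reads (bars, 95% Wilson intervals), highest at 11.3% in the untreated library of donor C; right, each library on the first 2 principal components, where that library lies at −174 on the first and the other 5 lie between 18.9 and 44.5.

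TNF against untreated cells asked how an inflammatory signal during myeloid differentiation alters the monocytes that form. Neutrophil and granule genes had lower fold changes in TNF cells, all 12 of the 12 measured members of the list. Their median log2 fold change was −2.63 (TNF minus untreated, 3 libraries against 3). Only in 4 of them did all 3 TNF libraries lie below all 3 untreated ones. MMP8, the collagenase of neutrophil granules, averaged 44.1 ± 32.5 CPM (SD, n = 3) in untreated and 3.81 ± 3.63 (SD, n = 3) in TNF cells. Targets and feedback regulators of NF-kB, the transcription factor that TNF receptors activate, lay higher in 19 of 25, with a median log2 fold change of 0.67. TNFAIP3, an NF-kB target that restrains the pathway, averaged 31.9 ± 14.6 CPM (SD, n = 3) in untreated and 63.1 ± 7.66 (SD, n = 3) in TNF cells. CD14, the marker used to isolate the cells, averaged 454.2 ± 210 and 482.8 ± 188.8 CPM (SD, n = 3 each).

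No single gene passed the threshold. Of 16005 genes, edgeR called 0 at an adjusted p under 0.05, with 386 at an unadjusted p under 0.05, where chance alone gives 800.25. DESeq2 called 15 (2 higher, 13 lower) and limma-voom called 0, with 672 at an unadjusted p under 0.05. With the donor as the replicate block, so that donors A and B alone inform the contrast, edgeR called 32 genes (7 higher, 25 lower). These calls, the blocked calls of genes below among them, end when the block is given the prior degrees of freedom of the unblocked fit (0 genes), and 2 genes pass when the donor numbers are crossed. Without the untreated library of donor C and no block, it called 6, all lower. All 3 TNF libraries lay above or below all 3 untreated libraries in 1482 genes (846 above, 636 below), 9.26% of those tested, where chance gives 10%.

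The 6 genes with the smallest p, none of which passed in edgeR with all 6 libraries and no block, were all lower in TNF cells. Each was lower in 3 of 3 TNF libraries against each untreated one. HP (ENSG00000257017; GRCh38 chromosome 16, 72054505 to 72061055), which encodes haptoglobin, averaged 42.4 ± 45.6 CPM (SD, n = 3) in untreated and 1.61 ± 0.443 (SD, n = 3) in TNF cells. Its log2 fold change was −4.71 (SE 0.758; adjusted p = 0.966, and 1.08e-10 with the block); it is close in sequence to HPR, and reads that aligned to both were not counted. THBS1 (ENSG00000137801; chromosome 15, 39581079 to 39599466), for the matrix glycoprotein thrombospondin 1, had 120.4 ± 55.6 and 10.3 ± 8.62 CPM (SD, n = 3 each), a log2 fold change of −3.55 (SE 0.622; adjusted p = 0.966, and 6.95e-05 with the block). PLAC8 (ENSG00000145287; chromosome 4, 83090048 to 83137075) and EMB (ENSG00000170571; chromosome 5, 50396192 to 50443248), which encodes the adhesion protein embigin, had log2 fold changes of −2.91 (SE 0.5) and −2.13 (SE 0.369). Their adjusted p was 0.966 each without and 7.52e-06 and 0.0131 with the block. NFE2 (ENSG00000123405; chromosome 12, 54292111 to 54301015), a transcription factor of megakaryocytes and red cells, and MAP2K6 (ENSG00000108984; chromosome 17, 69414697 to 69553865), a kinase of the stress-activated MAP kinase cascade, had log2 fold changes of −1.89 (SE 0.354) and −2.33 (SE 0.462). In edgeR with all 6 libraries they did not pass with or without the block. DESeq2 without a block called all 6 genes. Without untreated replicate C, HP and PLAC8 also passed in edgeR with no block (adjusted p = 0.0202 each).

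**Figure D2:**
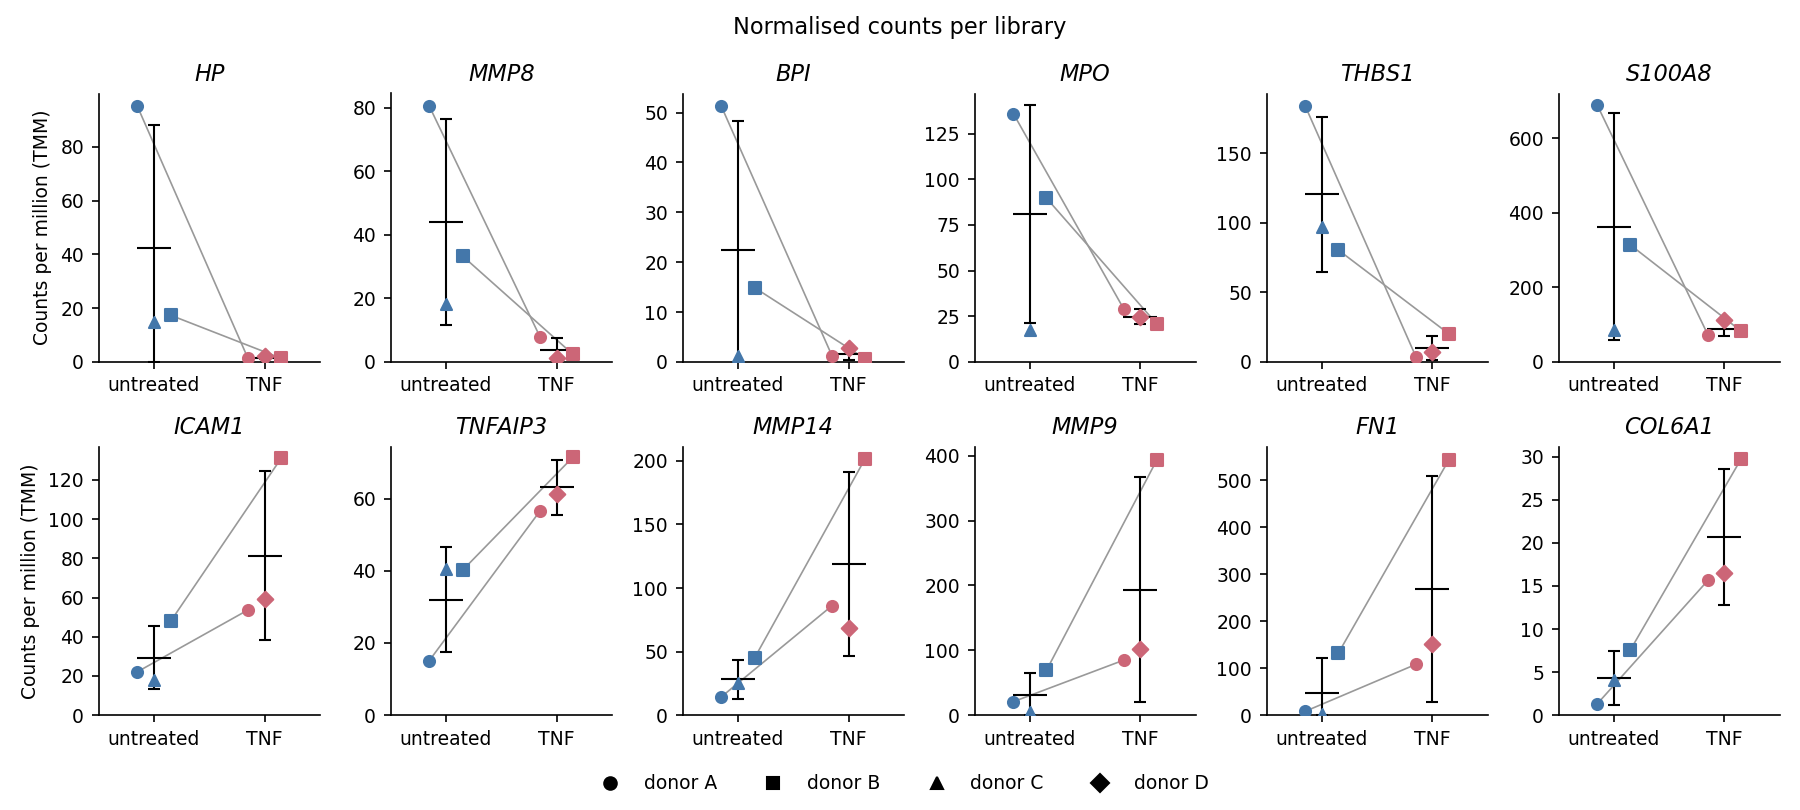
TMM-normalised counts (CPM) of 12 genes in each library (linear axes from 0); symbols mark donors, horizontal lines the mean and error bars 1 SD of 3 libraries, truncated at 0, and grey lines join the libraries of donors A and B. HP, MMP8, BPI, MPO, THBS1 and S100A8 have lower and the other 6 genes higher means in TNF cells; TNFAIP3 averages 31.9 in untreated and 63.1 in TNF cells.

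Of 29 gene lists tested with camera, 3 lay higher and 5 lower in TNF cells, and 0 kept their call with an estimated correlation, where the smallest adjusted p was 0.586. With the donor as the replicate block 4 lists lay higher and 5 lower, 5 of them in the same direction as without it, and again 0 kept their call with an estimated correlation. Without TNF replicate A 4 lay higher and 1 lower, without TNF replicate B 0 and 10, without untreated replicate B 2 and 3, and without untreated replicate C 1 and 6.

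The neutrophil and granule list, called the granule list below, had an adjusted p of 6.23e-12, and of 0.586 with an estimated correlation. Of its 12 tested members, 0 passed over all genes and 3 (MMP8, BPI and AZU1, all lower) adjusted over the list alone. With the block 7 passed adjusted over the list alone and 4 over all genes: MMP8, the neutrophil elastase ELANE, the bactericidal protein BPI and the arginase ARG1. MMP8 (ENSG00000118113; chromosome 11, 102711796 to 102727050) had a log2 fold change of −3.54 (SE 0.772), an adjusted p of 1 without and 4.8e-07 with the block. BPI (ENSG00000101425; chromosome 20, 38304150 to 38337505) averaged 22.4 ± 25.9 CPM (SD, n = 3) in untreated and 1.55 ± 1.08 (SD, n = 3) in TNF cells, an adjusted p of 1 without and 1.45e-09 with the block. Its log2 fold change of −3.84 (SE 1.11) was −2.38 without untreated replicate A. Without a block, DESeq2 called MMP8 and BPI (adjusted p = 0.000572 and 0.0451). ELANE had an adjusted p of 1 without and 2.01e-07 with the block, and ARG1 of 1 and 0.000293. The log2 fold change of ELANE, −2.77 (SE 1.67), turned to 0.47 with a random block in limma-voom and was −1.71 without untreated replicate A and −4.41 without TNF replicate D. MPO, the myeloperoxidase of azurophil granules, averaged 81 ± 59.8 and 24.7 ± 4.12 CPM (SD, n = 3 each) and did not pass over all genes either way (adjusted p = 0.0549 with the block). PRTN3, which encodes the granule protease proteinase 3, had reads in 2 libraries and was removed by the low-count filter, with 220, 210 and 0 reads in the untreated libraries of donors A, B and C and 0 in each TNF library. The untreated library with many undetected genes, that of donor C, also had 0 reads of ELANE, and its BPI level of 1.19 CPM lay within the range of the TNF libraries. MPO was detected there but low. It had 496 reads before scaling, fewer than the 792, 671 and 1024 in the TNF libraries of donors A, B and D.

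The NF-kB list had an adjusted p of 0.000709 in camera, and of 0.586 with an estimated correlation. None of its 25 members passed over all genes or adjusted over the list alone. ICAM1, an adhesion molecule that binds leukocyte integrins, averaged 29.3 ± 16.2 CPM (SD, n = 3) in untreated and 81.3 ± 43.1 (SD, n = 3) in TNF cells. NFKB2, which encodes an NF-kB subunit, had 25.4 ± 10.4 and 46 ± 4.79. BCL2A1, an NF-kB target that inhibits cell death, had the opposite sign, 60.4 ± 33.2 and 29.3 ± 13.8. Without TNF replicate B the list's median was 0.39 and its adjusted p 0.077. Inflammatory cytokines and chemokines had a median log2 fold change of 0.57 with 17 of 23 members higher, and the list did not pass (adjusted p = 0.0688). Its median was 0.03 with the block (adjusted p = 0.432) and −0.08 with the 4 libraries of donors A and B. The list passed as higher without a low-count filter (adjusted p = 0.00335), without untreated replicate A (0.0109) and without TNF replicate A (0.0203). Among them, IL1A averaged 3.26 ± 0.984 and 7.88 ± 0.563 CPM, and CXCL8, a chemokine that attracts neutrophils, 268.3 ± 107.8 and 181.8 ± 56.6. CCL2, which attracts monocytes, averaged 129.5 ± 27.4 and 108.8 ± 44.8, and IL1B 43.3 ± 28 and 68 ± 39.9. TNF itself averaged 4.08 ± 2.73 and 4.22 ± 1.16 CPM. Its receptors TNFRSF1A, at 32.2 ± 2.58 and 28.2 ± 1.7, and TNFRSF1B, at 88.7 ± 21.4 and 54 ± 4.29, did not pass, nor did the NF-kB inhibitor NFKBIA at 190 ± 44.3 and 302.9 ± 61.8.

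Matrix and tissue-repair genes lay in both directions. The fibrosis and tissue-repair list had a median log2 fold change of 0.14, with 10 of 18 members higher, and did not pass (adjusted p = 0.568); with the block it did (adjusted p = 0.00812, and 0.893 with an estimated correlation), as it did without a low-count filter (0.000248). Adjusted over the list alone, 1 member passed as higher and 1 as lower, MMP14 and THBS1, against 0 over all genes; with the block 5 passed as higher and 1 as lower adjusted over the list alone. MMP14 (ENSG00000157227; chromosome 14, 22836560 to 22849041), a membrane-bound matrix protease, averaged 28.1 ± 15.5 CPM (SD, n = 3) in untreated and 118.8 ± 72.3 (SD, n = 3) in TNF cells. Its log2 fold change was 2.08 (SE 0.518, adjusted p = 1, and 0.0418 with the block). DESeq2 called MMP14 without a block (adjusted p = 0.0203). MMP9, the gelatinase B gene, averaged 31.5 ± 33.7 and 193.7 ± 173.7 and did not pass over all genes either way (adjusted p = 0.182 with the block). FN1, for the matrix protein fibronectin, averaged 47.6 ± 73.7 and 267.8 ± 240.5 CPM, a log2 fold change of 2.49 (SE 1.26; adjusted p = 1, and 0.0441 with the block). It was 5.71 without untreated replicate B and 1.42 without TNF replicate B. The collagen VI chain genes COL6A1 and COL6A2, chosen after their values were seen, had log2 fold changes of 2.25 (SE 0.602) and 2.69 (SE 1.25). Their adjusted p was 1 each without and 0.00686 and 0.00446 with the block. COL6A2 was at 4.70 without untreated replicate B and 1.79 without TNF replicate B. LGALS3, for galectin 3, averaged 105.7 ± 47.4 and 45.8 ± 9.92 CPM. In the untreated library of donor C, COL6A2 had 0 reads and FN1 1.89 CPM.

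Markers of classical monocytes lay lower in 12 of 18, with a median log2 fold change of −0.61 (adjusted p = 0.0306, and 0.586 with an estimated correlation). Without untreated replicate B the adjusted p was 0.117, and without TNF replicate A it was 0.224. The median was −0.15 with the block (adjusted p = 4.77e-05), −0.14 with scaling to library size alone (0.0738), −0.11 with limma-voom (0.072) and −0.12 with a random block (0.125). S100A8, a calcium-binding alarmin of monocytes and neutrophils, averaged 363.3 ± 304.1 CPM (SD, n = 3) in untreated and 89.6 ± 20.8 (SD, n = 3) in TNF cells. Its partner S100A9 averaged 407.5 ± 348.4 and 106.7 ± 14.2, and in both genes the untreated library of donor C lay within the range of the TNF libraries or below it. S100A12, of the same family, had a log2 fold change of −1.60 (SE 1.51; adjusted p = 1, and 0.039 with the block). It turned to 1.02 with limma-voom and 1.54 with a random block, and was −0.73 without untreated replicate A and −2.45 without TNF replicate D. CCR2, the receptor for CCL2, averaged 6.45 ± 4.16 and 2.8 ± 2.46. Non-classical monocyte markers had a median of 0.41 with 10 of 14 higher (adjusted p = 0.0791, and 0.0459 with the block, where it was 0.893 with an estimated correlation). That list also passed with the stricter filter (adjusted p = 0.0247) and with counts divided by 2 (0.0311). FCGR3A, for the CD16 receptor and close in sequence to FCGR3B, averaged 6.37 ± 8.54 and 12.3 ± 10.9, and CX3CR1, the fractalkine receptor, 0.143 ± 0.248 and 0.482 ± 0.481. CD34, the marker of the starting cells, had 0 reads in all 6 libraries. By counting error alone this allows up to 0.0922 to 0.165 CPM in the libraries of donors A and B. In those of donors C and D commonly expressed genes also had 0 reads, so a 0 there sets no such limit.

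Dendritic cell markers lay higher in 6 of 8, with a median log2 fold change of 1.06 (adjusted p = 0.0104, and 0.586 with an estimated correlation). FSCN1, the actin-bundling protein of mature dendritic cells, averaged 14.6 ± 7.27 and 28 ± 12.3 CPM, and TCF4, a transcription factor of plasmacytoid dendritic cells, 14.2 ± 7.49 and 27.6 ± 9.32. The list's median was 0.68 (adjusted p = 0.188) without untreated replicate A, 0.81 (0.0815) without untreated replicate C, 0.59 (0.141) without TNF replicate B and 0.99 (0.066) without TNF replicate D. It was 0.57 (adjusted p = 0.232) with the 4 libraries of donors A and B. Megakaryocyte and platelet markers lay lower in 9 of 10, with a median of −1.10 (adjusted p = 0.0306, and 0.586 with an estimated correlation). ITGB3, the platelet integrin chain, averaged 22.4 ± 16.1 and 5.61 ± 7.39, and NRGN 13.9 ± 3.04 and 6.62 ± 2.08. The median was −0.23 (adjusted p = 0.245) without untreated replicate A, −1.25 (0.17) without untreated replicate B and −0.86 (0.0611) without TNF replicate A. It was −1.05 (adjusted p = 0.0875) with the stricter filter, −0.72 (0.109) with limma-voom, −0.64 (0.148) with a random block and −1.05 (0.0715) with counts divided by 2. The TNF library of donor D, with 2.72% of commonly expressed genes undetected, had 0 reads of ITGB3.

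Inflammasome and pyroptosis genes lay lower in 12 of 15, with a median log2 fold change of −0.40 (adjusted p = 0.0104, 0.586 with an estimated correlation, and 0.338 with the block). TXNIP, a thioredoxin-binding protein that can activate the NLRP3 inflammasome, averaged 430.9 ± 51.6 CPM (SD, n = 3) in untreated and 251 ± 47.4 (SD, n = 3) in TNF cells. The list's median was −0.22 (adjusted p = 0.369) without untreated replicate C and −0.48 (0.0964) without TNF replicate A. It was −0.46 (adjusted p = 0.251) with the 4 libraries of donors A and B and 0.02 (0.0994) with scaling to library size alone, which moved the median of all genes to 0.47. Cholesterol biosynthesis genes lay lower in 15 of 22, with a median of −0.20 (adjusted p = 0.0306, 0.586 with an estimated correlation, and 0.0629 with the block). MSMO1, a sterol demethylation enzyme, averaged 55.1 ± 16.7 and 25.7 ± 3.62. The adjusted p was 0.245 without untreated replicate A, where the median was 0.04, 0.0605 without untreated replicate C and 0.219 without TNF replicate A. With scaling to library size alone the median turned to 0.22 (adjusted p = 0.316), still below that of all genes; the call was also lost with limma-voom (0.072), a random block (0.0978) and the 4 libraries of donors A and B (0.0752). Cell cycle and replication genes lay higher in 19 of 25, with a median of 0.26 (adjusted p = 0.0306, and 0.87 with an estimated correlation), but with the block the median was −0.08 (adjusted p = 0.707). With the 4 libraries of donors A and B it was −0.03 (adjusted p = 0.749), without untreated replicate C −0.13 (0.356), without TNF replicate B −0.04 (0.44) and without untreated replicate B 0.40 (0.0777).

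**Figure D3:**
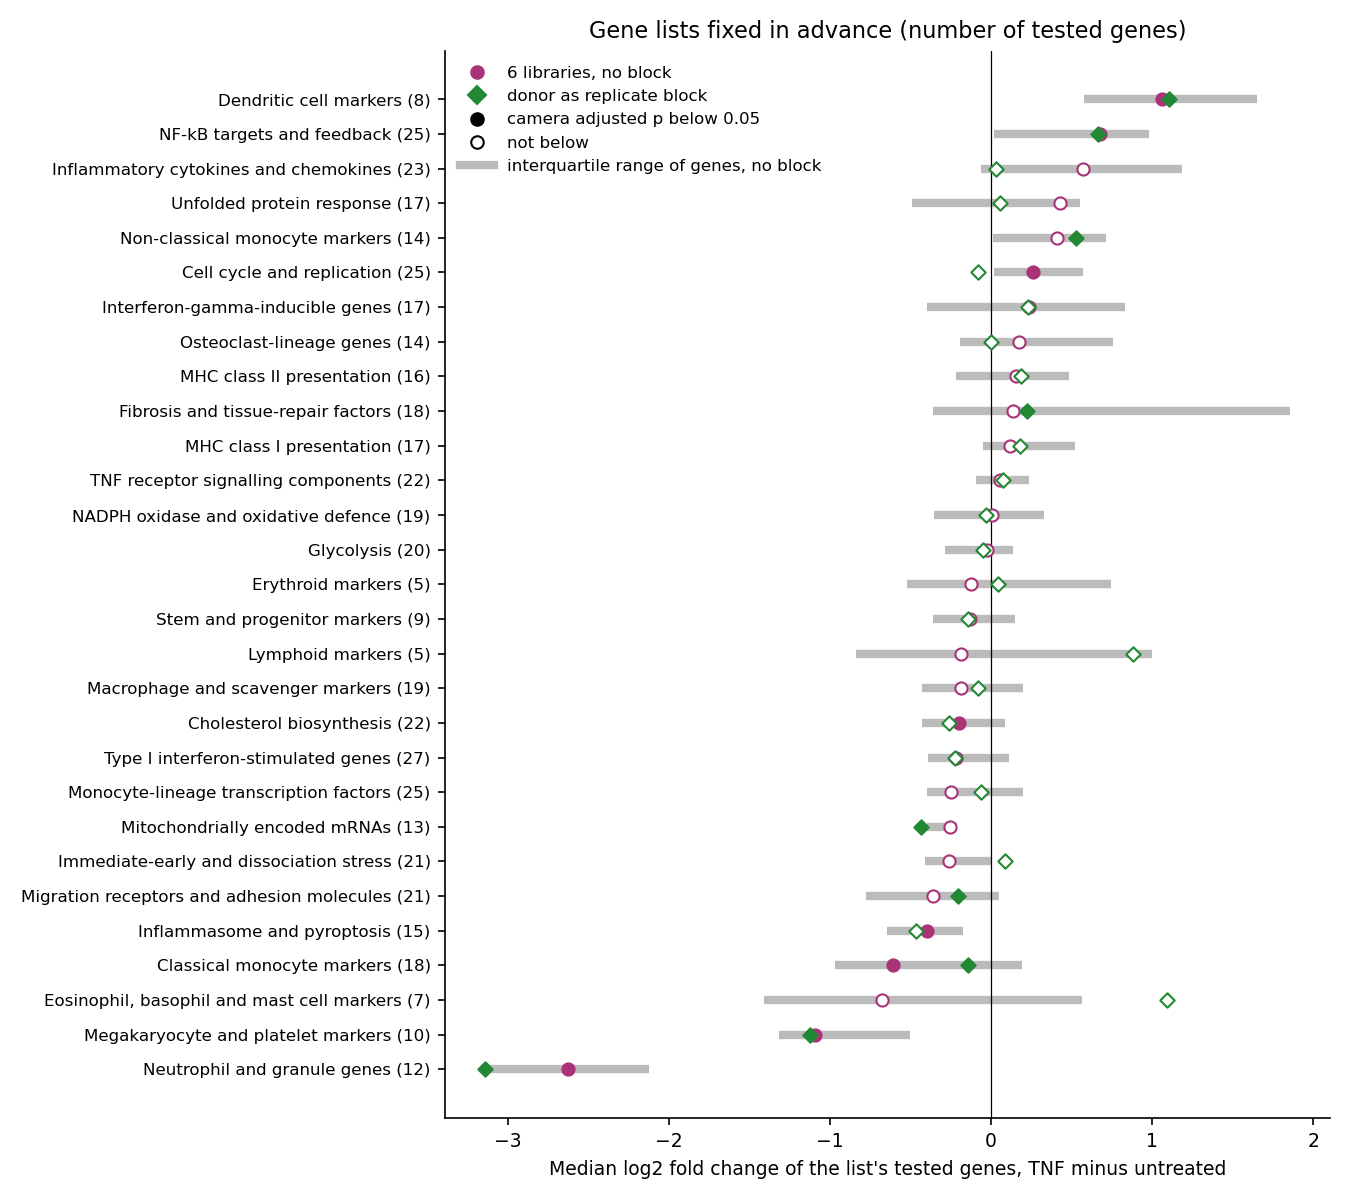
Median log2 fold change, TNF minus untreated, of the tested genes of each list without a block (circles) and with the donor as the replicate block (diamonds), filled where the camera adjusted p with a preset correlation is below 0.05; grey bars span the interquartile range of the genes without a block. Neutrophil and granule genes lie lowest, at −2.63, and dendritic cell markers highest, at 1.06.

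The other lists did not pass with all 6 libraries and no block. Migration receptors and adhesion molecules had a median log2 fold change of −0.36 (adjusted p = 0.0623, and 0.0158 with the block). FPR2, a formyl peptide receptor on that list, had a log2 fold change of −0.78 (SE 0.912; adjusted p = 1, and 0.0185 with the block), which turned to 0.18 without untreated replicate A and was −2.26 without TNF replicate D. CXCR4, the CXCL12 receptor, averaged 69.6 ± 27.6 and 32.8 ± 12.4 CPM. Mitochondrially encoded mRNAs had a median of −0.26 (adjusted p = 0.0688, and 0.00369 with the block). The migration list also passed with the 4 libraries of donors A and B (adjusted p = 0.000558), without untreated replicate C (0.0104) and without TNF replicate B (0.0296). The mitochondrial list passed in the same settings (adjusted p = 0.00884, 2e-05 and 1.92e-06, with medians of −0.34, −0.62 and −0.93) and without a low-count filter (0.0157). Both blocked calls ended with an estimated correlation, at an adjusted p of 0.893 each. Medians were −0.22 for type I interferon-stimulated genes (adjusted p = 0.434), 0.24 for interferon-gamma-inducible genes (0.473), 0.12 for MHC class I (0.501) and 0.15 for MHC class II presentation (0.578). Type I interferon-stimulated genes passed as lower with the 4 libraries of donors A and B (median −0.30, adjusted p = 0.0357), without untreated replicate C (−0.61, 0.000611) and without TNF replicate B (−0.45, 0.0296). MHC class I genes passed as higher without untreated replicate A (median 0.43, adjusted p = 0.0466). Medians were 0.003 for NADPH oxidase and oxidative defence (adjusted p = 0.967), −0.19 for macrophage and scavenger markers (0.831) and 0.17 for osteoclast-lineage genes (0.473). Monocyte-lineage transcription factors had a median of −0.25 (adjusted p = 0.122), glycolysis −0.02 (0.154), and immediate-early and dissociation stress genes −0.26 (0.154). As lower, the first and second of these passed without TNF replicate B (medians −0.21 and −0.31, adjusted p = 0.0359 and 0.0135). The last passed as lower without untreated replicate A (median −0.40, adjusted p = 0.0109). TNF receptor signalling components had a median of 0.06 and a mean of 0.15, while camera's direction was lower (adjusted p = 0.877). For the unfolded protein response the median was 0.43, the mean −0.09 and camera's direction lower (adjusted p = 0.855). Among other cell types, medians were −0.68 for eosinophil, basophil and mast cell markers (adjusted p = 0.538), −0.12 for erythroid markers with a mean of 0.02 (0.855) and −0.13 for stem and progenitor markers (0.401, and 0.0493 without a low-count filter). Lymphoid markers had a median of −0.19 and a mean of 0.27, with camera's direction lower (adjusted p = 0.295). With the block the median turned to 1.09 for the eosinophil, basophil and mast cell list, 0.88 for the lymphoid, 0.04 for the erythroid, 0.09 for the immediate-early and −0.03 for the NADPH oxidase list, and none of these passed. Of the 9 metallothionein genes 3 were measured, too few for a test. Outside the granule and fibrosis lists, 0 members of any list passed over all genes or adjusted over the list alone; with the block S100A12, FPR2 and MSR1, a macrophage scavenger receptor (log2 fold change −2.31, SE 1.54; adjusted p = 1, and 0.0053 with the block), passed over all genes. MSR1 turned to 0.40 with limma-voom and 0.94 with a random block, and was −1.16 without untreated replicate A and −3.42 without TNF replicate D. Adjusted over the list alone with the block, 4 classical monocyte, 2 migration, 2 macrophage, 1 megakaryocyte, 1 stem and progenitor and 1 lymphoid member passed as lower. Of the NADPH oxidase list 1 passed as higher, and of the osteoclast list 1 as higher and 1 as lower.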

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

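The fits without mitochondrial genes, with counts divided by 2, the other forms of the blocked fit and the settings for the principal components were chosen after seeing the data. With no block, edgeR called 0 genes with RLE size factors, library size alone, the stricter filter, no mitochondrial genes and counts divided by 2, and limma-voom called 0 with and without a random block. Without a low-count filter 63 passed (19 higher, 44 lower, all at least 2-fold, 15 list members), among more genes tested. DESeq2 called 15 (2 higher, 13 lower, all at least 2-fold, 4 list members), and the edgeR block 32 (7 higher, 25 lower, all at least 2-fold, 10 list members). The 4 libraries of donors A and B gave 1, a list member at least 2-fold lower. Leaving out each library gave 0 to 6 genes (0 to 6 lower and at least 2-fold, 0 to 1 list members), 6 only without untreated replicate C. The causes were not tested.

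Blocked alternatives called 27 to 39 genes, except 0 with the prior degrees of freedom of the unblocked fit, so the 32 calls rest on the prior that the block's 1 residual degree of freedom is given, and 2 with the numbers crossed between donors A and B. Of the 32, DESeq2 with the block shared 25 and limma-voom with the block 22.

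The lists called were 3 higher and 5 lower; 5 higher without a filter; 1 higher with the 4 libraries of donors A and B; 2 lower with library size alone, limma-voom and the random block; and 0 either way with an estimated correlation or fry. Leaving out each library gave 0 to 4 higher and 1 to 10 lower. Library size alone moved the median of all genes to 0.466 from 0.0593. The granule list kept its call in 16 of 18 alternatives and the NF-kB list in 15 of 18, losing it with an estimated correlation and fry, and NF-kB also without TNF replicate B. The first principal component took 66.8% with the 4 libraries, and 55% (without untreated replicate C) to 78% (without TNF replicate D) with each library left out; the cause was not tested.

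Some directions reversed. The cell cycle median was −0.08 with the block and −0.027 with the 4 libraries, and −0.131 to 0.707 with each library left out. With the random block the log2 fold changes were 0.467 for ELANE, 1.54 for S100A12, 0.935 for MSR1, −0.255 for MMP1 and 0.197 for PADI4, and with limma-voom 1.02 for S100A12 and 0.402 for MSR1. All of these genes have a library at 0 reads. The random block was fitted with an estimated correlation of −0.26 between libraries of a donor, so it treats them as less alike than unrelated ones. With the block TNF was at −0.0401 and CD14 at −0.00936, and TNF at −0.179 with the 4 libraries. With library size alone TNFRSF1A was at 0.261 and CCL2 at 0.146, less than the shift of all genes. Leaving out each library gave −0.219 to 0.731 for TNF, −0.279 to 0.473 for CD14, −0.561 to 0.0155 for CCL2, −0.102 to 3.01 for FCGR3A and −2.26 to 0.182 for FPR2. The causes were not tested. Depth limits genes with few reads, as mitochondrial transcripts left 6547944 to 12081230 other reads per library.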

Other observations

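The tests on LTF and LCN2, on the azurophil granule genes, on subunits of common cell machineries and on the other splits for single genes were chosen after the results were seen; those on depth, on fibroblast collagens and on the splits for lists and for the blocked fit were chosen before.

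Some genes called with the replicate block lie outside the lists and were chosen after their values were seen. PADI4, an enzyme that citrullinates histones in neutrophils, averaged 25.4 ± 31.1 CPM (SD, n = 3) in untreated and 1.01 ± 0.188 (SD, n = 3) in TNF cells (adjusted p = 1, and 1.45e-09 with the block); it passed without a block when untreated replicate C was left out (0.0151), and its log2 fold change of −4.64 (SE 1.56) was −3 without untreated replicate A and turned to 0.20 with a random block. MS4A3, a marker of granulocyte and monocyte progenitors, averaged 13.5 ± 12.7 and 0.692 ± 0.408 (adjusted p = 1, and 4.48e-08 with the block), and DESeq2 called it without a block. Higher in TNF cells were C3, the central complement component, at 13.4 ± 8.7 and 87.2 ± 95.8 (adjusted p = 1, and 0.0053 with the block), and MMP1, an interstitial collagenase, at 2.09 ± 3.16 and 13.3 ± 11.6 (adjusted p = 1, and 0.00268 with the block). The log2 fold change of MMP1, 2.69 (SE 1.87), was 5.62 without untreated replicate A and turned to −0.26 with a random block. That of C3, 2.7 (SE 0.889), was 1.30 without TNF replicate B, and the TNF library of donor D, at 11.4 CPM, lay below 2 of the 3 untreated ones. MMP1 had 0 reads in the untreated library of donor C and in the TNF library of donor D. Of the 32 blocked calls, 1 is a pseudogene copy of a mitochondrial gene, whose reads may in part come from the mitochondrial transcript. Without the genes of the mitochondrial genome 31 genes passed, all of them among the 32. That setting does not by itself remove such a copy, so it does not show where the copy's reads come from. SLC7A11, the cystine transporter, on the oxidative defence list, averaged 13.1 ± 10.2 and 40.4 ± 14.1, and IRF1, an interferon-response transcription factor, 29.2 ± 20.2 and 69.3 ± 1.5, and neither passed with or without the block.

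The lower granule genes in TNF cells had several candidate explanations. A difference in read depth was argued against, though the fit already scales to library size, so thinning could change little. After every library was thinned to equal numbers of non-mitochondrial reads, the median log2 fold change was −2.55 (camera adjusted p = 9.13e-12 at the preset correlation). Thinning does not equalise the number of distinct RNA molecules. Myelocytes, which carry abundant LTF and LCN2, were argued against as the main source of the granule reads in the untreated isolates. The ratio of LTF or LCN2 to MMP8 was at most 0.0383 in any untreated library. LCN2 had 0 reads everywhere, so LTF alone decides. LTF, with 74 reads in all 6 libraries together, itself followed the pattern. Scaled to non-mitochondrial reads (RPM), it had 3.67, 2.33 and 2.62 in the untreated libraries of donors A, B and C. In the TNF libraries of donors A, B and D it had 0, 0.937 and 0. A small share of myelocytes is thus not excluded. The list also holds FCGR3B and CXCR2, which are surface receptors of neutrophils and not granule genes, and both lay lower as well. Later neutrophils were not tested separately and are not excluded either. Fewer early granulocyte progenitors passing the CD14 isolation with TNF may account for the pattern and cannot be told apart from lower expression within CD14+ cells. The 5 azurophil genes had a median log2 difference of −2.75 within donors A and B, which both give. CTSG fell little in donor B, at −0.316. All 5 genes are on the granule list itself, so this value largely restates the pattern. A response of the monocytes themselves to TNF stays open as untested.

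The libraries of donors C and D stood apart from the other 4. Lower depth was argued against, since after thinning 11.4% of commonly expressed genes still had 0 reads in the untreated library of donor C, 2.84% in the TNF library of donor D and at most 0.875% in the others. A small number of distinct RNA molecules in the library may account for it: of 56 genes for proteasome, RNA polymerase II and eIF3 subunits, which all cells use, 6 (10.7%, 95% Wilson interval 5% to 21.5%) had 0 reads in the untreated library of donor C and 3 (5.36%) in the TNF library of donor D, against 0 in each of the others. Genes with few reads were also scarce in both libraries. Outside the mitochondrial genome, 13356 of 13836 genes with a read had at least 10 in the untreated library of donor C. In the TNF library of donor D it was 16258 of 16828. The untreated libraries of donors A and B had 13267 of 18723 and 17257 of 24949. Their TNF libraries had 17661 of 25863 and 16428 of 21859. Few distinct molecules, each read many times, would give this. A difference between the donors themselves was not tested.

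COL6A1, COL6A2, FN1 and MMP14 were higher with TNF in donors A and B, while THBS1, also a matrix gene, was lower. Fibroblasts in the TNF isolates were argued against: their most abundant collagens COL1A1, COL1A2 and COL3A1 reached at most 0.0248 times the level of COL6A1 in the TNF libraries of these donors, where COL6A1 had 52.3 and 90.6 reads, scaled to non-mitochondrial reads as RPM. COL3A1, DCN and LUM had 0 reads in all 6 libraries, but PDGFRB, also expressed by fibroblasts, had 2.2, 2.44 and 9.61 RPM in the TNF libraries of donors A, B and D against 0, 1.4 and 0 in the untreated ones. In the TNF library of donor D, COL1A1 had 7.29 RPM beside 56.8 for COL6A1, so a small share of such cells is not excluded there, though isolation by CD14 selects against them. Expression of these genes by the CD14+ cells under TNF stays open as untested.

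The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. For single genes, the real split gave 0 and the highest of the other splits 0, a comparison that a real count of 0 decides in advance. At an unadjusted p under 0.05 the real split gave 386 genes and the highest other split 1019, where chance alone gives 800.25. The real groups thus did not give the most genes, and the cause was not tested. For gene lists, the real split gave 8 and the highest other split 8, with 3 of the 10 splits at as many; among the 4 splits that part both pairs of donors A and B, the highest other gave 7. Camera gave the granule list an adjusted p of 6.23e-12 in the real split and of 1.15e-09 in another that parts both pairs. In the remaining splits it was 2.04e-06, 2.33e-05, 0.0269, 0.0362, 0.0469, 0.413, 0.498 and 0.679. Most groupings thus called this list at the preset correlation. The splits at 6.23e-12, 1.15e-09, 2.04e-06 and 2.33e-05 are those that keep the untreated libraries of donors A and B together. They share part of the real difference and are not groupings free of it. Its small p alone does not tie the pattern to TNF, although it was lowest in the real split. With the block, the real assignment gave 32 genes and the only other one, with the libraries of 1 shared donor swapped, gave 0; 1 of 2 assignments gave as many, and 2 are too few for such a share.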
